A study of Mus musculus with 18 samples.

How the data were processed

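Total RNA of J774 cells, a mouse macrophage line, was measured on 18 Affymetrix arrays, 3 in each of 6 groups: vehicle, estradiol, talc, talc plus estradiol, TiO2, and TiO2 plus estradiol. The deposited table holds an intensity per probe set and array on a linear scale, from 1.458 to 17256. The authors' notes name RMA as the tool, and give neither its version nor the level of summary nor the step back from the log2 scale. The quartiles of the arrays nearly match, as after a normalization between arrays. The plan made before the data were examined had taken the values to be log2, and since they were linear, log2 was taken here before any other step. Raw array files were not used here. For arrays, their number limits the precision, with a median standard error of 0.151 log2 units in comparisons of 3 arrays with 3 and of 0.213 in interactions.

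Probe sets were matched to gene symbols through the annotation of the array platform, which is older than the reference gene table, and 2247 symbols were updated through the synonyms in that table. A gene's value was the mean log2 intensity of its probe sets that carry a single symbol. There were 233753 such probe sets for 23102 genes, with a median of 8 per gene and 2303 genes with 1. Another 5106 probe sets carried several symbols and 30892 none, and these entered no gene value. A change in the use of exons within a gene is therefore averaged, and probe sets of a gene that move apart can cancel. No gene was filtered out.

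Group means were compared with limma 3.58.1 in R 4.3.3, with the data.table package (1.17.8) for reading. A single model with a mean per group was fitted to all 18 arrays (lmFit, eBayes), which gave 12 residual and 4.57 prior degrees of freedom. The 13 contrasts were each treatment against its control within an arm, the particles against each other, both combined treatments against vehicle, and the interactions of each particle with estradiol. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a contrast, two-sided, and passing genes that changed by at least 2-fold were also counted. The labels number the arrays through all groups and pair none of them; the replicate numbers used here were assigned within each group, so no paired analysis was made. Errors of log2 changes are standard errors of the model.

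Gene lists numbering 29, with 667 members written before the data were examined, were tested with camera at a preset correlation of 0.01 between genes, and again with a correlation estimated from the data; 641 members were measured, and the rest were not analysed here. The adjusted p of a list is over the lists of a contrast. Counts of members that passed are over all genes, and those adjusted over the list alone are marked as such. A further test, fry, was run on the same lists and is not printed.

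Named genes followed a rule fixed before the data were examined. Among passing genes whose arrays did not overlap between groups, the 12 largest rises and 12 largest falls of a contrast qualified, without predicted genes, clones and small RNA genes, which were only counted. So did the 4 leading members of a called list, the 3 genes with the smallest p where none passed, and all passing genes where 5 or fewer passed. Not every gene that qualified is printed.

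Correlations of log2 changes between contrasts were taken across genes, with 100 draws of simulated unchanged data for their chance value. Each gene was drawn independently, so the simulated ranges leave out correlation between genes and may be too narrow. The recovery of known changes was tested on simulated data with the spread of these arrays, in which 84% of genes changed by 1 log2 unit were called for talc against vehicle and 30% of those changed by 0.5. Every simulated contrast held many changed genes, which loosens the adjusted threshold. For contrasts in which few or no genes passed, such shares therefore overstate what could have been called. Alternatives tried were a filter on genes above the median level, the probe set with the highest mean per gene, each probe set on its own, quantile normalization, subtraction of array medians, an intensity trend with robust variance, array weights, a fit of only the arrays compared, and leaving out each array in turn. Added after the data were seen were a fit without the dimmest array, TiO2 plus estradiol replicate 3, for contrasts that do not involve it, the normalization and leave-out alternatives for gene lists, and the leave-out alternative for correlations. Other splits of the arrays were fitted in the same way.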

Results

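Expression was measured in J774 cells, a mouse macrophage line, 24 h after exposure to mineral particles, to estradiol, or to both. Cells in 24 wells plates received 10 µg per well of talc or of titanium dioxide (TiO2), or no particles, each with 2 µg/mL estradiol or with vehicle. This gave 6 groups of 3 arrays: vehicle, estradiol, talc, talc plus estradiol, TiO2, and TiO2 plus estradiol. The deposited intensities gave log2 values for 23102 genes. Array medians lay between 45.6 and 48.0 intensity units. Array numbers ran through the groups in order, and whether they give the order of processing is not stated. Any effect of that order cannot be told apart from group. The labels do not say whether the 3 arrays of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

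The 6 arrays of talc-treated cells separated from the other 12 on the first principal component, which held 20% of the variance. Their scores lay between 20.66 and 27.09, and those of all other arrays between -14.54 and -7.51. The estrogen receptor Esr1 had a mean log2 intensity of 5.83 ± 0.21 in vehicle-treated cells and 5.92 ± 0.13 with estradiol (SD, n = 3). Its mean over all arrays stood at percentile 60.6 of all genes. Esr2 stood at percentile 45.1, with 4.42 ± 0.23 in vehicle-treated cells, and the membrane estrogen receptor Gper1 at percentile 33.5, with 4.02 ± 0.13 (SD, n = 3).

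**Figure D1:**
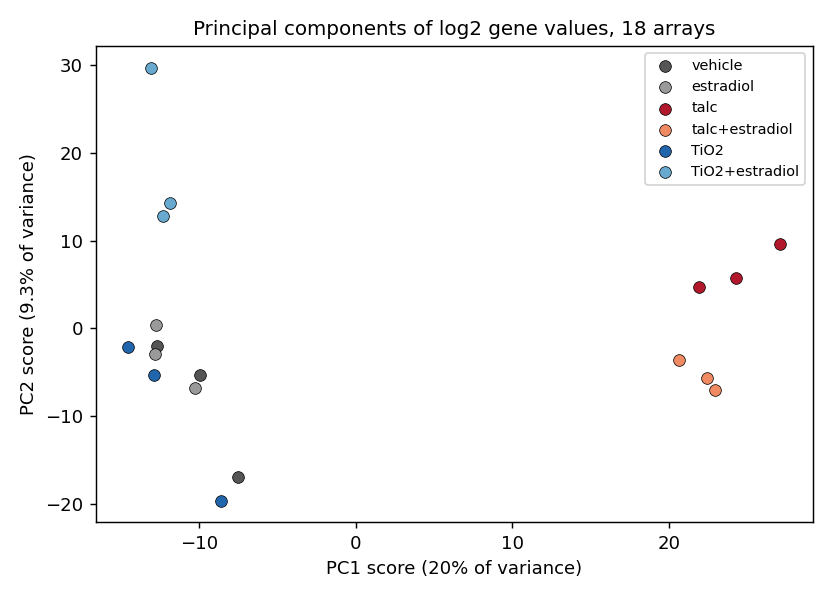
Principal component scores of the 18 arrays, computed on log2 gene values; each point is one array, colored by group, and the axes give component scores with no unit. The 6 talc arrays lie at PC1 scores of 20.66 and above, the other 12 at -7.51 and below.

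The first comparison asked what talc did to cells given vehicle. Among the genes that rose, Fos, an immediate early transcription factor, went from 4.36 ± 0.02 to 6.67 ± 0.19 log2 units (SD, n = 3), a log2 change of 2.31 ± 0.15 (SE, adjusted p = 1.9e-07). Cxcl2, a neutrophil-attracting chemokine, changed by 1.98 ± 0.13 (adjusted p = 1.9e-07) and Ptgs2, the inducible cyclooxygenase, by 1.88 ± 0.20 (adjusted p = 2e-05). The growth factor Pgf changed by 2.11 ± 0.21, Osbp2, an oxysterol-binding protein, by 1.96 ± 0.09, and the small nucleolar RNA host genes Snhg15 and Snhg12 by 2.65 ± 0.18 and 1.66 ± 0.16. The deepest fall was that of Tgfbi, a matrix protein induced by TGF-beta, from 8.74 ± 0.08 to 6 ± 0.11 (SD, n = 3), a log2 change of -2.74 ± 0.10 (adjusted p = 8.9e-11). The endosomal RNA receptors Tlr8 and Tlr7 changed by -2.09 ± 0.19 and -1.34 ± 0.12, Map2k6, a kinase upstream of p38, by -1.80 ± 0.13, the mannose receptor Mrc1 by -1.62 ± 0.14, and the ADP receptors P2ry12 and P2ry13 by -1.56 ± 0.19 and -1.47 ± 0.15.

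Further genes among the 12 largest rises were Stmn4 (1.77 ± 0.16), the C-type lectin Clec4n (1.58 ± 0.21), Il1rn, which encodes the antagonist of the interleukin-1 receptor (1.55 ± 0.17), Rrp12, a ribosome assembly factor (1.5 ± 0.13), and Gadd45b, a stress-inducible gene (1.49 ± 0.14). For Rrp12 the probe set with the highest mean gave -0.07, while 26 of its 27 probe sets moved upward. Among the 12 largest falls were also Abcd2, a peroxisomal fatty acid transporter (-1.72 ± 0.27), Cd300lg (-1.5 ± 0.17), Epsti1 (-1.48 ± 0.13), and Tnfsf13b, a B cell survival factor (-1.40 ± 0.14).

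Cell cycle lists moved furthest. Of 29 mitosis genes, 26 fell and 0 rose (29 and 0 adjusted over the list alone), with a median log2 change of -0.81 (camera adjusted p = 1.5e-40). The kinesins Kif11 (-1.15 ± 0.11) and Kif23 (-1.02 ± 0.11) and the spindle checkpoint kinases Bub1b (-0.95 ± 0.10) and Ttk (-1.03 ± 0.11) led the list. Of 30 DNA replication genes, 21 fell and 0 rose (27 and 0 adjusted over the list alone), with a median of -0.59 (camera adjusted p = 3.2e-27). These included the polymerase Pole (-0.86 ± 0.10), the helicase subunit Mcm3 (-0.73 ± 0.09) and the ribonucleotide reductase subunit Rrm2 (-0.92 ± 0.12). Among 23 targets of p53, 10 rose and 0 fell (12 and 2 adjusted over the list alone), with a median of 0.42 (camera adjusted p = 9.8e-08); Plk2 (0.85 ± 0.09), Aen (1.07 ± 0.11), Plk3 (0.96 ± 0.14) and Zmat3 (0.66 ± 0.13) had the largest statistics.

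Inflammatory lists also shifted. Of 24 feedback and target genes of NF-kB, 14 rose and 0 fell (14 and 0 adjusted over the list alone), with a median of 0.49 (camera adjusted p = 7.8e-13). Examples were the adhesion molecule Icam1 (0.87 ± 0.09), Traf1 (0.95 ± 0.11) and the mitochondrial superoxide dismutase Sod2 (0.72 ± 0.10). Of 29 cytokines and chemokines, 9 rose and 1 fell (12 and 1 adjusted over the list alone), with a median of 0.27 (camera adjusted p = 2.8e-05). Oncostatin M, encoded by Osm (1.03 ± 0.11), and the chemokine Ccl3 (0.60 ± 0.10) were among the former, and Il18 (-0.60 ± 0.15) was the latter. Type I interferon response genes went the other way: 6 of 38 fell and 0 rose (9 and 0 adjusted over the list alone), with a median of -0.19 (camera adjusted p = 4e-04). Stat2 (-0.53 ± 0.11), Ifi44 (-1.16 ± 0.25), Cmpk2 (-0.64 ± 0.15) and Trim30a (-0.76 ± 0.19) were the leading members. The brightest probe set of Trim30a gave 0.01.

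Of 27 oxidative stress genes controlled by NRF2, 6 rose and 2 fell (8 and 3 adjusted over the list alone), with a median of 0.17 (camera adjusted p = 0.0041). Thioredoxin reductase Txnrd1 (0.75 ± 0.09), the autophagy receptor Sqstm1 (0.62 ± 0.08), Gclm of glutathione synthesis (0.60 ± 0.09) and heme oxygenase Hmox1 (0.64 ± 0.11) rose, and Gstm1 (-0.47 ± 0.10) fell. Cholesterol synthesis genes fell in 6 of 21 cases and rose in 0 (7 and 0 adjusted over the list alone), with a median of -0.21 (camera adjusted p = 2.8e-05); they included Insig1 (-0.46 ± 0.09) and Idi1 (-0.58 ± 0.14). Of 34 lysosomal genes, 7 fell and 3 rose (8 and 4 adjusted over the list alone), with a median of -0.11 (camera adjusted p = 0.020). The protease Lgmn (-0.74 ± 0.09) and the cholesterol exporter Npc1 (-0.44 ± 0.09) fell, while the proton pump subunit Atp6v1h (0.80 ± 0.13) rose. The call of 2 further lists was lost with an estimated correlation. LXR target and fatty acid synthesis genes, 4 of 24 lower, had a median of -0.12 and an adjusted p of 0.0093, or 0.14 with an estimated correlation. Cytosolic heat shock genes, 5 of 17 higher with Hsph1 (0.82 ± 0.13) in front, had a median of 0.18 and an adjusted p of 0.0085, or 0.16 with an estimated correlation.

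The other 18 lists were not called, and several held members that moved apart. Among phagocytic and scavenger receptors 4 of 32 rose, such as Clec4d (0.97 ± 0.10), and 7 fell, such as the inhibitory Fc receptor Fcgr2b (-0.74 ± 0.09). Among 26 genes of the integrated stress response 4 rose and 5 fell; Ppp1r15a (1.12 ± 0.11) and Ddit3 (0.97 ± 0.12) rose, and the amino acid transporter Slc7a5 (-0.76 ± 0.11) fell. The median of that list was 0.01 while its camera test pointed down, with an adjusted p of 0.93. Of 30 matrix and growth factor genes 9 rose, with Adamts1 (0.84 ± 0.11), Pdgfb (0.74 ± 0.10) and Spp1 (0.65 ± 0.11) in front, and 3 fell. Of 23 macrophage identity genes 3 fell, namely Maf (-1.33 ± 0.13), Itgam (-0.57 ± 0.10) and Adgre1 (-0.79 ± 0.16), and 0 rose. In the lists of fibroblast, epithelial, lymphocyte and granulocyte markers 1 gene passed, Pdgfra (-0.67 ± 0.16).

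In all, 1955 of 23102 genes passed in limma at an adjusted p under 0.05, 910 of them higher and 1045 lower with talc, and 50 and 72 of these changed by at least 2-fold. The balance turned with the brightest probe set per gene (716 higher, 610 lower) and with array medians subtracted (1017 and 989). The count was 1251 when only the 6 arrays compared were fitted, 1233 without talc replicate 3, and 4041 probe sets passed when each was tested on its own. Of the 11 called lists, 9 held with an estimated correlation. The size of a camera p depends strongly on this setting. With talc pooled over the estradiol arms, mitosis genes had an adjusted p of 6.9e-39 with the preset correlation and of 0.00022 with an estimated one.

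**Figure D2:**
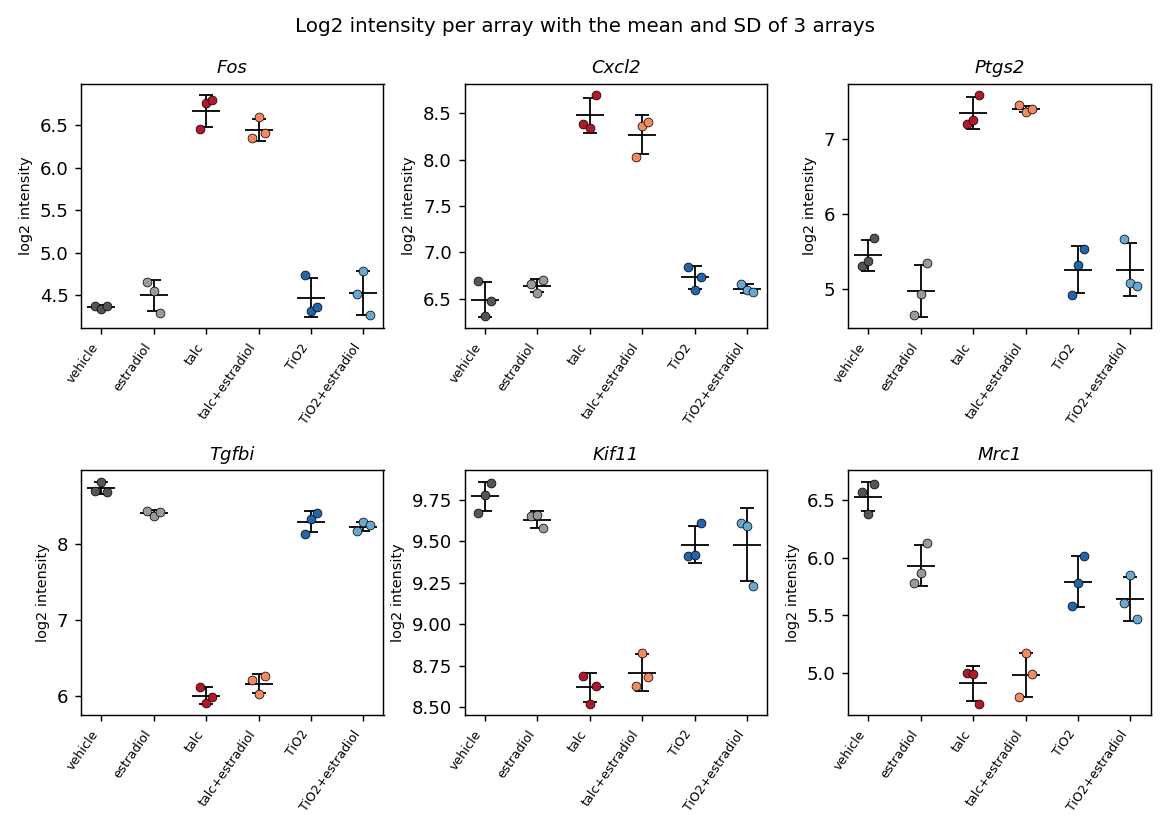
Log2 intensity of 6 genes on each of the 18 arrays; points are arrays, horizontal bars the group mean and error bars the SD of 3 arrays. Fos, Cxcl2 and Ptgs2 lie higher, and Tgfbi, Kif11 and Mrc1 lower, in both talc groups than in the other groups; Mrc1 has a mean of 6.53 in vehicle and 5.64 to 5.93 in the other groups without talc.

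The effect of talc was next read in cells that also received estradiol, against estradiol alone. Ptgs2 changed by 2.41 ± 0.20 (adjusted p = 3.9e-06), Fos by 1.95 ± 0.15 (adjusted p = 1.7e-06), Cxcl2 by 1.63 ± 0.13 and Pgf by 2.18 ± 0.21. Ddit3, a transcription factor of the stress response, changed by 1.59 ± 0.12, the complement component C3 by 1.51 ± 0.13, and Acod1, which makes itaconate, by 1.46 ± 0.19. Tgfbi again had the deepest fall, from 8.42 ± 0.03 to 6.16 ± 0.13 (SD, n = 3), a log2 change of -2.25 ± 0.10 (adjusted p = 2.1e-09). Maf, a macrophage transcription factor, changed by -1.38 ± 0.13, Lifr, a cytokine receptor subunit, by -1.28 ± 0.14, the adhesion molecule Mcam by -1.24 ± 0.12 and P2ry12 by -1.39 ± 0.19. The brightest probe set of Lifr gave 0.42, although 20 of its 22 probe sets moved downward.

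Of the mitosis genes 25 of 29 fell and 0 rose (28 and 0 adjusted over the list alone; median -0.67, camera adjusted p = 1.5e-32), with Ccnb2 (-0.72 ± 0.09) and Ndc80 (-0.91 ± 0.11) among them. DNA replication genes fell in 16 of 30 cases (25 adjusted over the list alone; median -0.49, camera adjusted p = 1e-21), and p53 targets rose in 8 of 23 and fell in 2 (12 and 2 adjusted over the list alone; median 0.32, camera adjusted p = 9.8e-06), where Mdm2 (0.91 ± 0.15) rose and Ddb2 (-0.61 ± 0.16) fell. NF-kB genes rose in 15 of 24 cases (17 adjusted over the list alone; median 0.54, camera adjusted p = 1.3e-17), led by Nfkbie (0.90 ± 0.09) and Nfkb2 (0.88 ± 0.10). Cytokines and chemokines rose in 11 of 29 and fell in 0 (12 and 1 adjusted over the list alone; median 0.28, camera adjusted p = 6.7e-07), with Csf1 (0.94 ± 0.14) added to those above. NRF2 genes rose in 8 of 27 and fell in 1 (9 and 2 adjusted over the list alone; median 0.14, camera adjusted p = 0.0020). These 6 calls held with an estimated correlation.

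A further 3 calls did not. Integrated stress response genes rose in 7 of 26 cases and fell in 1, with a median of 0.16 and an adjusted p of 0.0010 (adjusted p = 0.11 with an estimated correlation). Heat shock genes rose in 3 of 17, with a median of 0.22 (adjusted p = 0.091 with an estimated correlation). The 16 genes of estradiol metabolism and targets of the aryl hydrocarbon receptor had a median of -0.19 (adjusted p = 0.062 with an estimated correlation), and 1 of them, Ugt1a7c (-0.54 ± 0.12), fell. Type I interferon genes were not called here: 3 of 38 fell, and the list had a median of -0.12 and an adjusted p of 0.20. In all 1647 genes passed in limma, 953 higher and 694 lower. Leaving out single arrays gave 904 genes without talc plus estradiol replicate 3, 1034 without its replicate 1, and 1010 and 1050 without estradiol replicates 2 and 1. A fit of only the compared arrays gave 988, the brightest probe set per gene 856, and genes above the median level 2483. The share of calls that were higher was 57.9% in the main fit, 41.9% with the brightest probe sets and 43.7% with each probe set on its own.

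These talc comparisons share no array, and their log2 changes across all genes, which are not independent replicates, had a Pearson correlation of 0.517 and a Spearman correlation of 0.391. Simulated data with no effect gave -0.001. The Pearson correlation was 0.256 with the brightest probe set per gene and 0.764 among genes above the median level. A total of 538 genes were higher and 525 lower in both, where independent lists drawn from all genes would share 37.5 and 31.4. These chance values are too low, since 1825 of the 1955 and 1532 of the 1647 passing genes lay above the median level. A single gene passed with opposite signs, the sulfotransferase Chst15, which was named after its values were seen. It changed by 0.47 ± 0.11 with talc alone and by -0.53 ± 0.11 with talc in the presence of estradiol, and the test of that difference gave an adjusted p of 0.24. In both talc comparisons and in both direct comparisons of talc with TiO2, 433 genes were higher and 333 lower throughout; within each arm these comparisons share the arrays with talc, so they are not independent.

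**Figure D3:**
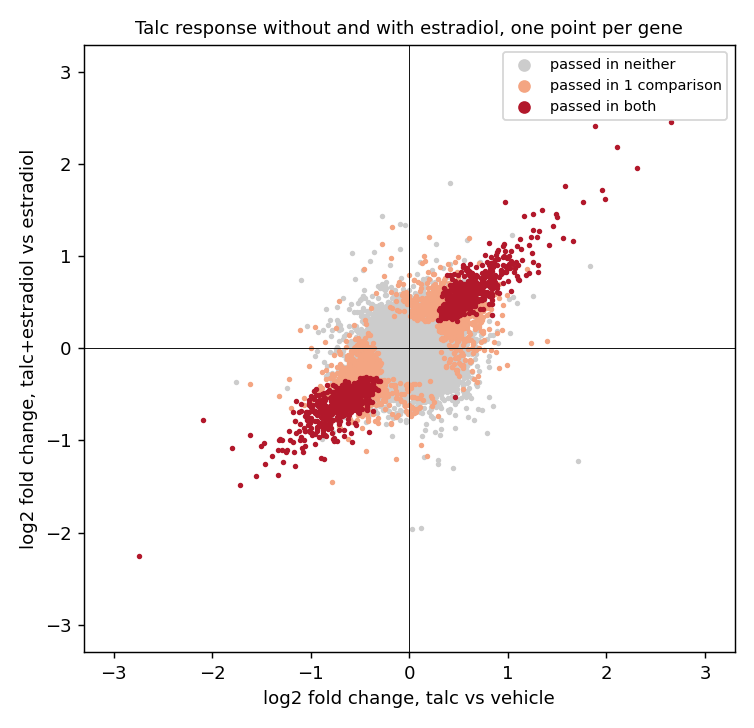
Log2 fold change of each of 23102 genes with talc against vehicle (horizontal axis) and with talc plus estradiol against estradiol (vertical axis); color marks genes that passed in neither, in 1 or in both comparisons. Of the genes passing in both, 538 lie in the upper right, 525 in the lower left and 1, Chst15, in the lower right.

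TiO2 was the other particle of the design, given at the same mass per well. In cells given vehicle, no gene passed against vehicle alone in limma, and 1886 genes (8.16%) had an unadjusted p under 0.05. The smallest p belonged to Gpr183, an oxysterol receptor, at 8.40 ± 0.05 against 7.79 ± 0.10 (SD, n = 3), a log2 difference of 0.62 ± 0.09 with an adjusted p of 0.082. Sertad3 (0.67 ± 0.12) and Ttll3 (0.68 ± 0.12) followed, with adjusted p = 0.23 each, and the brightest probe set of Ttll3 gave -0.01. Integrated stress response genes stood lower as a list, with a median of -0.17, 0 of 26 passing (6 lower adjusted over the list alone) and a camera adjusted p of 7.1e-06, or 0.17 with an estimated correlation. The cystine transporter Slc7a11 had -0.73 ± 0.15 and Chac1 -0.56 ± 0.13. Hypoxia and glycolysis genes had a median of 0.09, with 0 of 28 passing, and an adjusted p of 0.0036, or 0.36 with an estimated correlation, and were not called without vehicle replicate 3. In 97.1% of genes the 95% interval of the difference lay within 2-fold either way. The share was 95.6% for talc against vehicle, where 1955 genes passed, so it does not tell a contrast with few changes from one with many. Leaving out TiO2 replicate 2 or 3 or vehicle replicate 3 gave 1 passing gene. In simulated arrays for this comparison, 92% of genes changed by 1 log2 unit were recovered and 28% of those changed by 0.5. A total of 169 genes were called in those arrays, which loosens the adjusted threshold. Recovery would be lower in the real contrast, where none passed.

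In cells given estradiol, TiO2 against estradiol alone gave 1 passing gene, D630033O11Rik, a gene without a functional name, given because 5 or fewer passed. It stood at 3.89 ± 0.08 against 3.04 ± 0.09 (SD, n = 3), near the dim end of the scale, with a difference of 0.85 ± 0.12 and an adjusted p of 0.039, and 2 of its 3 probe sets rose. It no longer passed when any of the 6 arrays compared was left out. A total of 2059 genes (8.91%) had an unadjusted p under 0.05. The mitosis list had a median of -0.11 with 0 of 29 members passing and a camera adjusted p of 0.042, or 0.71 with an estimated correlation; Hmmr had -0.38 ± 0.14. That list was not called after quantile normalization or subtraction of array medians, nor without TiO2 plus estradiol replicate 2 or 3, estradiol replicate 1, TiO2 replicate 1, or vehicle replicate 1 or 3. The log2 changes of TiO2 in the absence and presence of estradiol had a correlation of 0.013 across genes, with -0.024 to 0.03 in simulations without an effect. It was 0.148 among genes above the median level, and -0.033 to 0.057 when single arrays were left out. Genes that rose with talc in the estradiol arm, 953 in number, had a median change of 0.41 in talc against vehicle and of 0.01 in TiO2 against vehicle. Genes that fell with talc in the vehicle arm, 1045 in number, had a median change of -0.42 with talc and of -0.11 with TiO2 in the estradiol arm, and 80.2% of them were lower with TiO2 there. The TiO2 plus estradiol arrays had the lowest upper quartiles of all arrays, and a part of brightness in this share was not tested. In the other direction, the 694 genes that fell with talc in the estradiol arm had a median of -0.01 in TiO2 against vehicle, with 52.9% lower, and the 910 that rose in the vehicle arm had -0.02 with TiO2 in the estradiol arm.

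Because talc and TiO2 were both set against the vehicle arrays, their changes share chance values. Their correlation of 0.288 compares with 0.5 in simulated unchanged groups, and their covariance of 0.0163 with a simulated 0.0169. In the estradiol arm the correlation was 0.272 and the covariance 0.0153, against a simulated 0.0169.

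**Figure D4:**
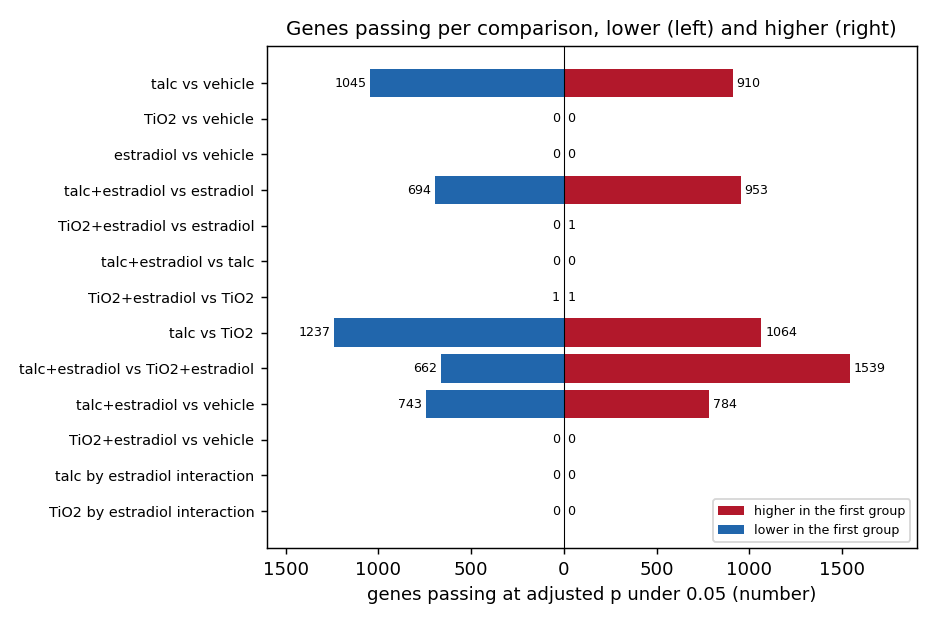
Number of genes passing at an adjusted p under 0.05 in each of 13 comparisons; bars to the right count genes higher in the first group, bars to the left genes lower. The 5 comparisons of a talc group with a group without talc have 1527 to 2301 passing genes, and the other 8 have 0 to 2.

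The direct comparison of the particles in cells given vehicle gave 2301 genes, 1064 higher and 1237 lower with talc than with TiO2. Il1rn was higher by 1.91 ± 0.17, Fos by 2.20 ± 0.15, Ptgs2 by 2.07 ± 0.20 and Rgs1, a regulator of G protein signaling, by 1.54 ± 0.19. Tgfbi differed by -2.30 ± 0.10, P2ry12 by -1.69 ± 0.19, Tnfsf13b by -1.58 ± 0.14 and the cell cycle inhibitor Cdkn2c by -1.29 ± 0.11. Mitosis genes were lower in 28 of 29 cases (29 adjusted over the list alone; median -0.72) and NF-kB genes higher in 16 of 24 (17 adjusted over the list alone; median 0.52). The checkpoint ligand Cd274 was higher by 1.18 ± 0.17 and the class I molecule H2-T23 lower by 0.98 ± 0.14 log2 units. Of 21 cholesterol synthesis genes 8 were lower and 1 higher (12 and 1 adjusted over the list alone; median -0.33, camera adjusted p = 1e-06). Lists of 12 were called in all, and 7 held with an estimated correlation, namely cytokines and chemokines, NF-kB, lysosome, cholesterol synthesis, mitosis, DNA replication and p53 targets. Adjusted p rose to 0.10 for interferon and NRF2 genes, 0.18 for the integrated stress response, 0.14 for heat shock genes and 0.20 for macrophage identity with an estimated correlation. The count was 1011 with only the compared arrays fitted and 1353 without talc replicate 3, the brightest probe set per gene gave 1480, and 4297 single probe sets passed.

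With estradiol present, 2201 genes differed between the particles, 1539 higher and 662 lower with talc. Osm was higher by 1.39 ± 0.11, Ppp1r15a by 1.33 ± 0.11, Pinx1, a nucleolar telomerase inhibitor, by 1.68 ± 0.17, and Il1b, an inflammasome-processed cytokine, by 1.08 ± 0.18. Tgfbi differed by -2.07 ± 0.10, the sialyltransferase St6gal1 by -1.09 ± 0.16, Map2k6 by -1.05 ± 0.13 and Lifr by -1.04 ± 0.14; the brightest probe set of Lifr gave 0.18. Mitosis genes were lower in 20 of 29 cases (26 adjusted over the list alone; median -0.53), p53 targets higher in 10 of 23 (13 adjusted over the list alone; median 0.33) and NF-kB genes higher in 15 of 24 (20 adjusted over the list alone; median 0.46). Of 8 called lists 6 held with an estimated correlation; the exceptions were the integrated stress response (adjusted p = 0.27 with an estimated correlation) and heat shock genes (adjusted p = 0.15 with an estimated correlation). Genes that were higher made up 69.9% of the calls, 60% after quantile normalization, 65.5% after subtraction of array medians, and 38.8% of 1248 calls with the brightest probe set per gene. The TiO2 plus estradiol arrays had upper quartiles of 7.87, 7.86 and 7.80 log2 units, and all other arrays 7.89 to 7.96. The count was 812 with only the compared arrays fitted, and 1221 and 1457 without talc plus estradiol replicates 3 and 1, and 3701 single probe sets passed.

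Estradiol alone gave no passing gene against vehicle in limma, and 1124 genes had an unadjusted p under 0.05, or 4.87% of those tested. The smallest p belonged to Jsrp1, which stood at 5.33 ± 0.08 against 4.75 ± 0.09 (SD, n = 3; difference 0.58 ± 0.11, adjusted p = 0.53). Slc45a2 (-0.62 ± 0.12) and Fbxw20 (-0.99 ± 0.20) followed with the same adjusted p. None of the 24 estrogen receptor and responsive genes passed. Integrated stress response genes stood lower as a list, with a median of -0.18 and a camera adjusted p of 5.9e-12, and 0.013 with an estimated correlation; 0 of 26 members passed, and 4 were lower adjusted over the list alone. Ddit3 had -0.54 ± 0.12 and Slc7a11 -0.59 ± 0.15. LXR and fatty acid synthesis genes had a median of -0.07, with 0 of 24 passing, and an adjusted p of 0.023, or 0.39 with an estimated correlation, and were not called without estradiol replicate 1 or 2 or vehicle replicate 3. Without estradiol replicate 3, 4 lists were called in place of 2. In simulated arrays for this comparison 86% of genes changed by 1 log2 unit were recovered and 20% of those changed by 0.5. With 164 genes called there, the adjusted threshold was looser than in the real contrast, so these shares are too high for it.

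Added to talc, estradiol gave no passing gene against talc alone in limma, and 1521 (6.58%) had an unadjusted p under 0.05. Chst15 (-0.66 ± 0.11) and Gem, a small GTPase (-0.55 ± 0.10), had an adjusted p of 0.43, and Inka1 (0.63 ± 0.12) one of 0.58; the brightest probe set of Inka1 gave -0.16. Cholesterol synthesis, mitosis and macrophage identity lists stood higher, with medians of 0.11, 0.10 and 0.12 and an adjusted p of 0.0027 each. No member passed, and with an estimated correlation the adjusted p was 0.47 for each. Without talc replicate 3 none of these 3 lists was called, and without talc plus estradiol replicate 3, 5 lists were.

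Added to TiO2, estradiol gave 2 passing genes against TiO2 alone in limma, and 3012 (13.04%) had an unadjusted p under 0.05. D630033O11Rik was higher by 0.85 ± 0.12 (adjusted p = 0.038), and Lipt1, a lipoyltransferase, was lower, at 4.23 ± 0.09 against 5.13 ± 0.23 (SD, n = 3), by 0.90 ± 0.13 log2 units (adjusted p = 0.041). The brightest of the 7 probe sets of Lipt1 gave 0.09. Single probe sets, array weights and a fit of the compared arrays gave 0 genes, as did leaving out TiO2 replicate 2 or 3 or TiO2 plus estradiol replicate 1 or 2. Without TiO2 plus estradiol replicate 3, 1 gene passed, and the brightest probe set per gene gave 19, with neither D630033O11Rik nor Lipt1 among them in either case. The mitosis list had a median of -0.10 with 0 of 29 passing and an adjusted p of 0.020, or 0.41 with an estimated correlation, and it was not called after quantile normalization, nor without TiO2 replicate 1 or 3 or TiO2 plus estradiol replicate 3. Between the estradiol comparisons, which share no array, log2 changes had correlations of -0.042 (alone and with talc), 0.037 (alone and with TiO2) and -0.206 (with talc and with TiO2) across genes. Simulations without an effect gave -0.027 to 0.026, -0.025 to 0.021 and -0.024 to 0.036 for these pairs. They drew each gene independently, so shifts that genes of an array share are not in these ranges. A value outside them is therefore no test of an effect of estradiol. The first pair had 0.01 without vehicle replicate 3, -0.018 without estradiol replicate 2 and -0.025 without its replicate 1, and the second had -0.027, -0.002 and -0.004 without vehicle replicate 3, estradiol replicate 2 or TiO2 replicate 3, so these values rest on single arrays. The third lay between -0.235 and -0.152 when single arrays were left out.

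Talc and estradiol together against vehicle gave 1527 genes, 784 higher and 743 lower. This balance turned with the brightest probe set per gene (390 and 435), with each probe set on its own (740 and 1213) and with only the compared arrays (345 and 442). It also turned without talc plus estradiol replicate 1 or 3 or vehicle replicate 1 or 2. Snhg15 changed by 2.49 ± 0.18, Zfp36, which destabilizes cytokine mRNAs, by 1.58 ± 0.20, C3 by 1.48 ± 0.13, Tgfbi by -2.58 ± 0.10, Mrc1 by -1.54 ± 0.14 and Cd109, a co-receptor of TGF-beta, by -1.31 ± 0.12. Mitosis genes fell in 25 of 29 cases (26 adjusted over the list alone; median -0.70), DNA replication genes in 19 of 30 (26 adjusted over the list alone; median -0.50), while NF-kB genes rose in 14 of 24 (16 adjusted over the list alone; median 0.46). Of 13 called lists, 6 held with an estimated correlation: mitosis, DNA replication, NF-kB, cytokines and chemokines, NRF2 genes and p53 targets. The others were interferon (adjusted p = 0.14 with an estimated correlation), lysosome (0.075), cholesterol synthesis (0.28), LXR and fatty acid synthesis (0.23), heat shock (0.23), hypoxia and glycolysis (0.23) and estradiol metabolism (0.062). Without talc plus estradiol replicate 2, or without vehicle replicate 3, 8 lists were called in place of 13. The count was 787 with only the compared arrays, 825 with the brightest probe set per gene and 2292 among genes above the median level. It was 798 and 948 without talc plus estradiol replicates 3 and 1, and 918 and 915 without vehicle replicates 1 and 2.

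TiO2 and estradiol together against vehicle gave no passing gene in limma, and 2908 (12.59%) had an unadjusted p under 0.05. The mannose receptor Mrc1 stood at 5.64 ± 0.19 against 6.53 ± 0.13 (SD, n = 3; difference -0.89 ± 0.14, adjusted p = 0.099), and Gemin4 (0.91 ± 0.15), measured by 1 probe set, had the same adjusted p. Lists of 5 kinds stood lower, each with 0 members passing. They were interferon genes (median -0.18, adjusted p = 0.0095), LXR and fatty acid synthesis (-0.12, 0.0074), mitosis (-0.18, 0.00037), DNA replication (-0.10, 0.022) and the integrated stress response (-0.17, 2.4e-05). With an estimated correlation the adjusted p was 0.19, 0.28, 0.28, 0.40 and 0.19. Without vehicle replicate 2, 3 lists were called, among genes above the median level 1, and with the brightest probe set per gene 2. Ifi44 had -1.19 ± 0.25 and Slc7a1, a cationic amino acid transporter, -0.47 ± 0.12.

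Whether estradiol changed the response to talc was tested as an interaction. No gene passed in limma, and 1460 (6.32%) had an unadjusted p under 0.05; Chst15 had the smallest p (-1 ± 0.16, adjusted p = 0.24). Lists of 6 kinds stood higher with camera: the integrated stress response (median 0.20, adjusted p = 1.5e-05), mitosis (0.15, 0.00092), cholesterol synthesis (0.15, 0.0028), LXR and fatty acid synthesis (0.11, 0.022), macrophage identity (0.12, 0.022) and DNA replication (0.09, 0.036). With an estimated correlation the adjusted p was 0.20, 0.29, 0.29, 0.29, 0.29 and 0.48. In the stress list Shmt2 had 0.56 ± 0.15 and Ddit3 0.62 ± 0.16. Without vehicle replicate 3, 2 lists were called in place of 6. In simulated arrays, interactions of 1 log2 unit were recovered in 56% of genes and of 0.5 in 6%. With 126 genes called there, the adjusted threshold was looser than in the real contrast, so these shares are too high for it.

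The interaction of TiO2 and estradiol gave no passing gene in limma, and 1860 (8.05%) had an unadjusted p under 0.05. D630033O11Rik had the smallest p (1.17 ± 0.17, adjusted p = 0.057), followed by Il18bp (-1.11 ± 0.18, adjusted p = 0.18), which encodes an interleukin-18 inhibitor, and Ms4a6b (1.54 ± 0.27, adjusted p = 0.20). Quantile normalization or subtraction of array medians gave 1 passing gene, and leaving out TiO2 replicate 2 gave 4. The brightest probe sets of Il18bp and Ms4a6b gave 0.30 and -0.66. The integrated stress response list stood higher (median 0.20, adjusted p = 0.00018) and hypoxia and glycolysis genes lower (median -0.15, adjusted p = 0.012), with 0 members passing in either list and an adjusted p of 0.36 for both with an estimated correlation. Hypoxia and glycolysis genes were not called without estradiol replicate 2 or vehicle replicate 3. In simulated arrays 58% of interactions of 1 log2 unit were recovered. That share too is higher than the real contrast would give, since 132 genes were called in the simulated one.

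**Figure D5:**
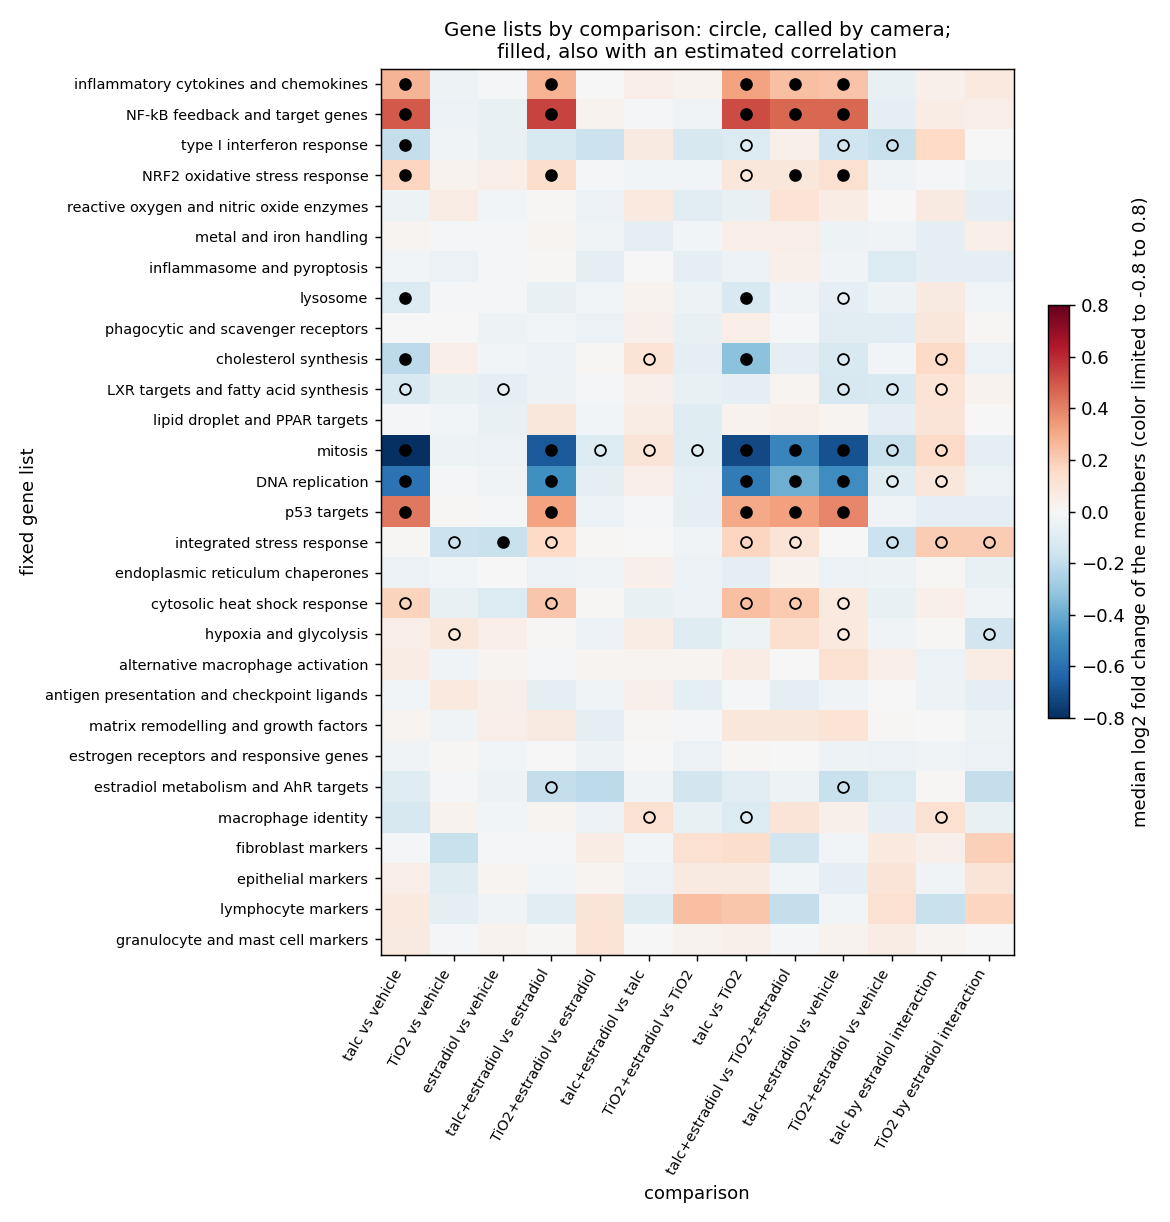
Median log2 fold change of the measured members of 29 fixed gene lists (rows) in 13 comparisons (columns), as color; a circle marks a list called by camera at an adjusted p under 0.05, a filled one a call that also held with an estimated correlation. The 5 columns of a talc group against a group without talc hold 34 of the 35 filled circles.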

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

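The tests of explanations for the stress response pattern were chosen before their results were seen, except the one that leaves out single vehicle arrays.

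Lists of 6 kinds were singled out because estradiol changed their shift with talc, by the interaction test with a preset correlation. They were the integrated stress response (adjusted p = 1.5e-05, median 0.20), mitosis (0.00092, median 0.15), cholesterol synthesis (0.0028, median 0.15), LXR targets and fatty acid synthesis (0.022, median 0.11), macrophage identity (0.022, median 0.12) and DNA replication (0.036, median 0.09). With TiO2 the integrated stress response (0.00018, median 0.20) and hypoxia and glycolysis (0.012, median -0.15) differed in the same way. None was called with an estimated correlation, where the adjusted p lay between 0.20 and 0.48 for talc and was 0.36 for TiO2. No member gene passed in either interaction in limma. Among 100 splits, 37 gave as many called lists as the real 6 for talc, and the highest other split gave 12; for TiO2 20 of 100 gave as many as the real 2, and the highest other gave 5. The splits shuffled the arrays of all groups in an interaction, so an effect of the particle itself could enter the other counts. They therefore cannot decide the matter, and chance cannot be excluded for either count.

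The stress response list was weighed further, since it stood lower in estradiol (median -0.18) and in TiO2 (-0.17) than in vehicle. Both contrasts, and both interactions above, use the same vehicle arrays, so they are not independent observations. Without vehicle arrays, the list was not called in TiO2 plus estradiol against estradiol or against TiO2. With an estimated correlation its camera adjusted p was 0.39 for estradiol pooled over the particle arms and 0.87 for TiO2 pooled over the estradiol arms. Its levels relative to the mean of all arrays were 0.07, 0.14 and 0.08 in the vehicle arrays, -0.16, -0.15 and -0.08 in estradiol, and -0.17, -0.13 and -0.05 in TiO2. A single vehicle array standing apart is argued against, as the median in estradiol against vehicle was -0.2 at the least negative when each vehicle array was left out in turn. Brightness left between arrays by the normalization is argued against, since the median in estradiol against vehicle was -0.18 after quantile normalization. Both values are for estradiol against vehicle, so they do not cover the lower list in TiO2. The place of the vehicle arrays, all first in the order of array numbers, was not tested and cannot be separated from the group. A biological effect of estradiol and of TiO2 on this pathway may be involved and stays open as well. In the TiO2 plus estradiol arrays the levels were -0.09, -0.11 and -0.02. In the talc arrays they were 0.09, 0.10 and 0.09 and with talc plus estradiol 0.09, 0.11 and 0.07, near those of vehicle. The list was thus not lower in every group that received estradiol, nor in every group after vehicle in the array order. Talc itself moved members of this list, so the levels in the talc groups do not decide between the causes left open.

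Probe sets that entered no gene value also carried a signal with talc against vehicle. Of 30892 probe sets without a symbol 126 passed, 41 higher and 85 lower, or 0.41%. Of 5106 with several symbols 70 passed, 23 higher and 47 lower, or 1.37%, against 1.64% of those with 1 symbol. No explanation was tested for these.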

How the results depend on the processing

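Chosen after the data were seen were the fit without TiO2 plus estradiol replicate 3 for contrasts not involving it, both renormalizations of gene lists, and the leave-out ranges of lists and correlations. The causes of the changes given here were not tested, except that a fit of only the arrays compared has 4 residual degrees of freedom in place of 12, and that a filter tests fewer genes.

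Among the settings that give a value per gene, directions of named genes reversed with the probe set with the highest mean alone; testing each probe set on its own gives no value per gene. Of 638 values of named genes, 436 kept direction and side of the threshold there, 179 lost the call, 1 gained it and 22 reversed. With quantile normalization 629 of 638 were unchanged in this sense, with array medians subtracted 626, with the variance trend 626, with array weights 630, and with only the compared arrays 512. Of the 1955 genes that passed in talc against vehicle, 920 passed with the same sign for the highest probe set, and 76 had the other sign there, whether or not they passed, so the value of a gene holds for the mean of its probe sets.

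The values that reversed with that probe set were, in talc against vehicle, Rrp12 -0.07, Trim30a 0.01 and Derl3 0.02; in TiO2 against vehicle, Ttll3 -0.01; in talc plus estradiol against estradiol, Lifr 0.42 and Pdgfra 0.27. Against talc alone, talc plus estradiol gave Inka1 -0.16, Pmvk -0.1, Itgam -0.02 and Adgre1 -0.05, and against TiO2 plus estradiol it gave Lifr 0.18. TiO2 plus estradiol gave Lipt1 0.09 against TiO2, and Ifi47 0.02, Dlgap5 0.04, Mcm10 0.09 and Pola1 0.22 against vehicle. In the interactions these were Abca7 -0.03, Ccne1 -0.46 and Adgre1 -0.17 for talc, and Il18bp 0.3, Ms4a6b -0.66 and Bnip3l 0.05 for TiO2.

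Counts that moved by over 1.5 times are given by setting, and count genes except where each probe set was tested. Among genes above the median level they were 2483 for talc plus estradiol against estradiol, 2292 for talc plus estradiol against vehicle, 1 for TiO2 against vehicle and 2 for TiO2 plus estradiol against vehicle. With the highest probe set per gene they were 856 (talc plus estradiol against estradiol), 825 (against vehicle), 1248 (against TiO2 plus estradiol) and 1 (against talc), 1480 for talc against TiO2, and 0 and 19 for TiO2 plus estradiol against estradiol and against TiO2. Each probe set on its own, among many more tests, gave 4041 probe sets (talc against vehicle), 4297 (talc against TiO2), 3701 (talc plus estradiol against TiO2 plus estradiol), 1 (talc plus estradiol against talc), 0 (TiO2 plus estradiol against TiO2) and 3 (TiO2 plus estradiol against vehicle). With only the compared arrays the counts were 1251 (talc against vehicle), 1011 (talc against TiO2), 988, 812 and 787 (talc plus estradiol against estradiol, TiO2 plus estradiol and vehicle), and 0 for TiO2 plus estradiol against estradiol or TiO2. Array medians subtracted gave 1 for TiO2 against vehicle and 1 for the TiO2 interaction, and quantile normalization 1 for that interaction. The variance trend gave 2 for TiO2 against vehicle, 0 for TiO2 plus estradiol against estradiol and 4 against vehicle. Array weights gave 0 for TiO2 plus estradiol against TiO2.

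Leaving out single arrays gave 1233 to 2061 genes for talc against vehicle, lowest without talc replicate 3, and 904 to 1765 for talc plus estradiol against estradiol, lowest without talc plus estradiol replicate 3. The ranges were 1353 to 2419 for talc against TiO2 (lowest without talc replicate 3), 1221 to 1738 for talc plus estradiol against TiO2 plus estradiol and 798 to 1608 against vehicle (both lowest without talc plus estradiol replicate 3). They were 0 to 1 for TiO2 against vehicle, 0 to 2 for TiO2 plus estradiol against TiO2, 0 to 4 for the TiO2 interaction (highest without TiO2 replicate 2) and 0 to 0 for estradiol against vehicle, talc plus estradiol against talc, TiO2 plus estradiol against estradiol and against vehicle, and the talc interaction. The highest counts for talc against vehicle, estradiol and TiO2 came without TiO2 plus estradiol replicate 3, the dimmest array, which enters those contrasts only through the shared spread.

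Of the 75 calls of gene lists, 35 held with an estimated correlation, 57 among genes above the median level, 53 with the highest probe set, 75 with the variance trend, 71 after quantile normalization and 73 with array medians subtracted. Leaving out single arrays gave 61 to 79 calls, lowest without vehicle replicate 3. The correlation of the talc contrasts across genes was 0.764 above the median level and 0.256 with the highest probe set, that of the TiO2 contrasts 0.148 above the median level, and that of the estradiol contrasts with talc and with TiO2 -0.296 above the median level. Without single arrays they were 0.468 to 0.517 (talc), -0.033 to 0.057 (TiO2), and, for estradiol, -0.071 to 0.01 (alone and with talc), -0.027 to 0.075 (alone and with TiO2) and -0.235 to -0.152 (with talc and with TiO2). Of all log2 values, 29.7% lay under 4.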

Other observations

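Chosen after results had been seen were the scan of gene families, the pooled comparisons and the endotoxin test.

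Some groups of genes that share a symbol stem shifted with talc in both arms, in a scan of 275 such groups that rests on symbols and not on fixed lists. With the preset correlation 12 were called in both talc comparisons in the same direction, 8 higher and 4 lower, and with an estimated correlation 0 of the 12 were called in both. The direction of each median held after quantile normalization and after subtraction of array medians. Of 11 Utp genes of the small subunit processome 8 rose without and 7 with estradiol, with medians of 0.47 and 0.48 (adjusted p = 0.40 and 0.22 with an estimated correlation), led by Utp4 (0.84 ± 0.10 and 0.93 ± 0.10, SE). Of 14 proteasome Psmd genes 3 rose in each arm, with medians of 0.31 and 0.34 (adjusted p = 0.20 and 0.13 with an estimated correlation). Of 48 mitochondrial ribosome Mrpl genes 8 and 10 rose, with medians of 0.19 and 0.31 (adjusted p = 0.64 and 0.33 with an estimated correlation). Other ribosomal protein genes were not called in both arms. Without and with estradiol the adjusted p was 0.77 and 0.77 for Rps genes, 0.021 and 0.55 for Rpl genes (3 and 2 higher), and 0.086 and 0.00025 for Mrps genes (5 and 7 higher), and none of these was called with an estimated correlation. Of 10 genes with the stem Mcm, which include subunits of the replication helicase, 8 and 6 fell, with medians of -0.55 and -0.41 (adjusted p = 0.20 and 0.22 with an estimated correlation). Some of them, such as Mcm3, are also in the fixed DNA replication list.

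Pooled over the estradiol arms, talc (6 arrays against 6) gave 3416 genes, 1830 higher and 1586 lower, with Tgfbi at the smallest p. Only the real split among 100 gave as many, 1 of 100, and the highest other gave 217. The pooling was chosen after the same arrays had given 1955 and 1647 genes within the arms, so this outcome could be foreseen. It restates those calls and is no independent evidence against a chance draw. The splits cannot tell talc from a difference between cultures or places in the array order that goes with the groups. TiO2 pooled gave 0 genes in limma, with 2065 at an unadjusted p under 0.05; 100 of 100 splits gave as many and the highest other gave 1. Estradiol pooled over the particle arms (9 against 9) gave 0 genes in limma, with 1288 at an unadjusted p under 0.05; 100 of 100 splits gave as many and the highest other gave 2. With a real count of 0 every split gives as many, so these splits say nothing about chance.

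For single comparisons of 3 arrays with 3 there are 10 splits, too few for a share under 0.05. The real count of genes and the highest of the other splits were 1955 and 0 for talc against vehicle, 1647 and 1 for talc plus estradiol against estradiol, 2301 and 0 for talc against TiO2, 2201 and 0 for talc plus estradiol against TiO2 plus estradiol, and 1527 and 1 for talc plus estradiol against vehicle. In each of these 1 split of 10, the real one, gave as many. For TiO2 against vehicle, estradiol against vehicle and talc plus estradiol against talc both counts were 0, and for TiO2 plus estradiol against vehicle they were 0 and 1; 10 of 10 gave as many, as they must with a real count of 0. For TiO2 plus estradiol against estradiol they were 1 and 1, with 2 of 10 as large. For TiO2 plus estradiol against TiO2 the real count was 2 and another split gave 28, 25 higher and 3 lower, with 2 of 10 as large. That split set TiO2 plus estradiol replicates 1 and 2 with TiO2 replicate 3 against the other 3 arrays, which points to a structure of the samples, for which no test was run. For the interactions 100 of 100 splits gave as many genes as the real 0, as they must, and the highest others were 2 for talc and 1 for TiO2.

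The numbers of called lists, real and highest other, were 11 and 5 for talc against vehicle, 9 and 7 for talc plus estradiol against estradiol, 12 and 6 for talc against TiO2, 8 and 6 for talc plus estradiol against TiO2 plus estradiol, and 13 and 6 for talc plus estradiol against vehicle. They were 2 and 1 for estradiol against vehicle, 1 and 0 for TiO2 plus estradiol against estradiol, 3 and 1 for talc plus estradiol against talc, and 5 and 1 for TiO2 plus estradiol against vehicle. In all of these 1 of 10 splits gave as many. For TiO2 against vehicle they were 2 and 2, with 2 of 10 as large, and for TiO2 plus estradiol against TiO2 1 and 1, with 3 of 10.

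With talc against vehicle 14 of 24 NF-kB targets rose, while 6 of 38 interferon response genes fell and 0 rose. In talc plus estradiol against estradiol the interferon list was not called (adjusted p = 0.20, 3 lower), and in talc against TiO2 its call was lost with an estimated correlation (adjusted p = 0.10). The list was also called lower without talc, in TiO2 plus estradiol against vehicle. With TiO2 pooled over the estradiol arms its camera adjusted p was 0.046, or 0.74 with an estimated correlation. Both of these calls were lost with an estimated correlation, and TiO2 gave no such call within either arm. Endotoxin on the talc, acting through the receptor arm that induces interferon, stays open. The mean of the interferon list, -0.21 in talc against vehicle, is part of the pattern itself and cannot exclude it, and the other arm gave no call. For the NF-kB list a change in dim genes alone is argued against, as it had an adjusted p of 4.3e-09 among genes above the median level. This value does not bear on the interferon list. An effect of the particle itself may be involved and was not separated from other properties of the talc preparation.

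More genes were higher than lower in talc plus estradiol against TiO2 plus estradiol, 69.9% of those that passed. Brightness left between arrays by the normalization may account for part of this: quantile normalization brought the share to 60%, the bound set beforehand, which it met by less than the rounding, with 1189 of 1983 genes higher. The dimmest array, TiO2 plus estradiol replicate 3, is argued against as the whole source, as the share without it was 66.1%. With the probe set with the highest mean per gene the balance was the other way, with 38.8% of 1248 genes higher, so the direction of the excess depends on how probe sets are summarised. The remaining excess stays open, and TiO2 plus estradiol is also the last group in the order of array numbers.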
